A study of Mus musculus with 6 samples.

How the data were processed

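RNA was measured by sequencing in BV2 cells, an immortalised mouse microglial line, from 3 libraries labelled GCH1 knockdown and 3 labelled negative control. Per the labels' protocols, the knockdown cells were infected for 48 hours with an adenovirus carrying a short hairpin RNA (shRNA) against GCH1. The treatment text calls the other cells the adenoviral negative control, while the series text calls them wild type, and it is unclear from these labels whether the control cells received a virus. RNA was extracted with TRIzol, depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols, and sequenced on an Illumina NovaSeq instrument, per the series text. Libraries were grouped by the genotype label and named by group and title number. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

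The deposited table gives 1 value per gene and library with no stated unit. The values behave as FPKM that the authors computed: they are not whole, they sum to between 224291 and 230292 per library, and the value times the transcript length falls on whole multiples of a fixed step in genes with a single transcript. The submitters' processing notes name HISAT2, StringTie and edgeR, without versions or the role of each. These notes name the human build hg38, although every identifier in the table is a mouse Ensembl gene. The annotation release and the strand setting are not given in the sources used here. The table holds 12327 genes, and in each of them the mean of at least 1 group reached 0.501 FPKM or more, so weakly expressed genes were not analysed here. No count was given, so the depth of each library was only estimated, from the step described above. In 1470 to 1489 genes per library, 77.9% to 79.3% of values lay within 0.1 of a whole step, against 20.0% by chance. The step corresponds to 5.25 to 5.58 Gb (gigabases) of aligned sequence in the control libraries and 6.32 to 7.61 Gb in the knockdown libraries. No column belonged to a sample outside this series.

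Gene symbols, biotypes and coordinates were taken from GENCODE M21 (assembly GRCm38) by gene identifier without its version, which matched 12300 identifiers. Of these, 10904 also matched with the version, 10738 were protein-coding and 1562 noncoding or pseudogenes. Genes were tested with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, on log2(FPKM + 1). The 12222 genes at 0.5 FPKM or more in at least 3 of the 6 libraries entered the fit, which had no covariate. Genes past a Benjamini-Hochberg (BH) adjusted p of 0.05 were called, and those with at least a 1.5-fold change were also counted. Fold changes are knockdown minus control on the log2 scale, and the pseudocount of 1 shrinks those of weakly expressed genes.

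A total of 36 gene lists was fixed for microglial state, inflammation, tetrahydrobiopterin (BH4) metabolism, redox and energy metabolism, proliferation, stress, noncoding RNA and markers of other cell types. The 29 lists with at least 5 measured members were tested against all other genes with limma's camera at a preset correlation of 0.01, BH adjusted over the lists. Camera with an estimated correlation and limma's fry, which tests whether a list moved on balance without comparison to other genes, were run beside it. Named genes are Gch1 and every measured BH4 synthesis gene, up to 10 called genes per direction with groups that did not overlap and a mean of at least 1 FPKM in the higher group, up to 3 noncoding genes per direction by the same rule, and up to 4 members of each list with the smallest p. The values of 1 gene that this rule names are not reported here. Groups, lists, the tests of genes and lists, the rule for named genes and the alternatives were set before the data were examined. The 2 alternatives named as added below, the heptamer search and the tests weighed in the closing observations were not among them.

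The alternatives were a block for the replicate number, each library left out in turn, no filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 0.5, median-of-ratios scaling, quantile normalization, robust moderation, no mean-variance trend, an estimated correlation and fry. After the data were seen, a correction for the GC content and length of transcripts was added, in which a loess curve with a span of 0.3 was removed from each library. Camera without genes holding a particular 3′ UTR heptamer was added too. Heptamers were scored in annotated 3′ UTRs of at least 50 bases by regressing the rank of the corrected fold change on presence, UTR length and UTR GC content, for heptamers present in at least 50 genes. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

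The test was tried on simulated data of 12222 genes with the means and spread of the comparison of knockdown with control, in 10 runs with 200 changed genes each. It called 20.6% of the genes changed by 1.25-fold, 59.2% at 1.5-fold, 83.4% at 2-fold and 93.4% at 3-fold. False calls were 4% of all calls. The noise was drawn independently for each gene from the variance model that the test itself assumes. A share of false calls near the threshold was therefore built in, and trends shared across genes were not simulated. In 10 of 10 simulated runs the heptamer scan ranked a planted heptamer first. The planted shift was larger than the median shift of the heptamer's genes reported below. These runs therefore do not show whether a shift of that smaller size would be found.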

Results

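Expression was measured in 6 libraries of ribosomal RNA-depleted total RNA from BV2 mouse microglial cells, 3 with an adenoviral hairpin against GCH1 for 48 hours and 3 controls. GCH1 is GTP cyclohydrolase I, the rate-limiting enzyme in the synthesis of BH4, a cofactor of nitric oxide synthases and aromatic amino acid hydroxylases. The comparison asked how the transcriptome of these cells differs when Gch1 is knocked down. Library sums were 224291 to 230292 FPKM and medians 6.28 to 6.44 FPKM. Across genes Pearson's r between any pair of libraries was 0.989 to 0.993 on log2(FPKM + 1). Estimated depth was higher in the knockdown libraries (mean 6.93 Gb of aligned sequence) than in the controls (5.45 Gb), with no overlap between the groups.

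The targeted gene fell to under 50% of its control level, while 9 other genes of 12222 passed the test. Gch1 was at 7.12 ± 0.20 FPKM in the controls and 3.19 ± 0.25 FPKM in the knockdown libraries (SD, n = 3 each), which is 44.8% of control. The BH4-recycling enzyme Qdpr, the zinc finger gene Zfp422, the vesicle protein gene Tmem230, vitamin K epoxide reductase Vkorc1, ferritin light chain Ftl1 and the small heat shock protein gene Hspb7 fell too. The polarity scaffold gene Mpp5, the mitochondrial glutaredoxin Glrx2 and Mir17hg, the host transcript of a microRNA cluster, rose.

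Gch1 (ENSMUSG00000037580.10; GRCm38 chromosome 14, 47153895 to 47189413, minus strand) was at 6.89, 7.22 and 7.23 FPKM in the control libraries and 3.20, 2.93 and 3.43 FPKM in the knockdown libraries, in the direction of the labels in all 6. Its log2 fold change was -0.96 (SE 0.06, limma BH adjusted p = 0.00542). The two-sided exact permutation p over the 6 libraries was 0.1, the smallest that 3 against 3 can give.

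Of 12222 genes tested, 10 passed a limma BH adjusted p of 0.05, 3 higher and 7 lower. Of these, 7 changed by at least 1.5-fold on the scale of log2(FPKM + 1) (2 higher and 5 lower). Glrx2, at 168.3% of control in FPKM, fell short on that scale (log2 fold change 0.51). With the replicate number as a block, 0 genes passed, and the limma BH adjusted p of Gch1 was 0.06. In each of the 10 genes that passed without the block, the 3 knockdown libraries lay on the same side of all 3 controls. At an unadjusted p under 0.05 there were 1380 genes (791 higher and 589 lower), and 2243 genes (18.4%) had groups that did not overlap, against 10% by chance. The median log2 fold change over all genes was 0.01.

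The largest decrease among the 10 genes was that of Zfp422 (ENSMUSG00000059878.12; chromosome 6, 116624016 to 116628999, minus strand), from 5.15 ± 0.47 to 0.953 ± 0.126 FPKM (SD, n = 3 each), with a log2 fold change of -1.65 (SE 0.08, limma BH adjusted p = 0.00152). Tmem230 (chromosome 2, 132239492 to 132247807) fell from 10.2 ± 0.56 to 5.02 ± 0.34 FPKM, log2 -0.89. Vkorc1 (chromosome 7, 127893063 to 127895617) fell from 19.3 ± 1.31 to 10.3 ± 0.81 FPKM, log2 -0.84. Ftl1 (chromosome 7, 45457944 to 45459884), among the most abundant transcripts here, fell from 887 ± 23.1 to 630 ± 17.4 FPKM, log2 -0.49, and Hspb7 (chromosome 4, 141420779 to 141425311) from 75.8 ± 0.87 to 58.3 ± 1.65 FPKM, log2 -0.37. Reads of Ftl1 may be shared with its near-identical copies, and Ftl1-ps1, looked up after the values were seen, was at 105 FPKM in the controls and 97.9 FPKM after knockdown (limma BH adjusted p = 0.614). Mpp5 (chromosome 12, 78748907 to 78840714) rose from 5.64 ± 0.35 to 9.68 ± 0.40 FPKM, log2 0.69. Glrx2 (chromosome 1, 143716338 to 143749676) rose from 1.68 ± 0.03 to 2.83 ± 0.10 FPKM, log2 0.51. For Tmem230, Vkorc1, Ftl1, Mpp5, Hspb7 and Glrx2 the limma BH adjusted p ranged from 0.0074 for Tmem230 to 0.0362 for Glrx2. Zfp422, Gch1 and Tmem230 passed with each of the 6 libraries left out in turn, Vkorc1 passed in 5 of the 6, Ftl1 and Qdpr in 3, Mpp5 in 2, and Hspb7, Glrx2 and Mir17hg in 0.

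**Figure D1:**
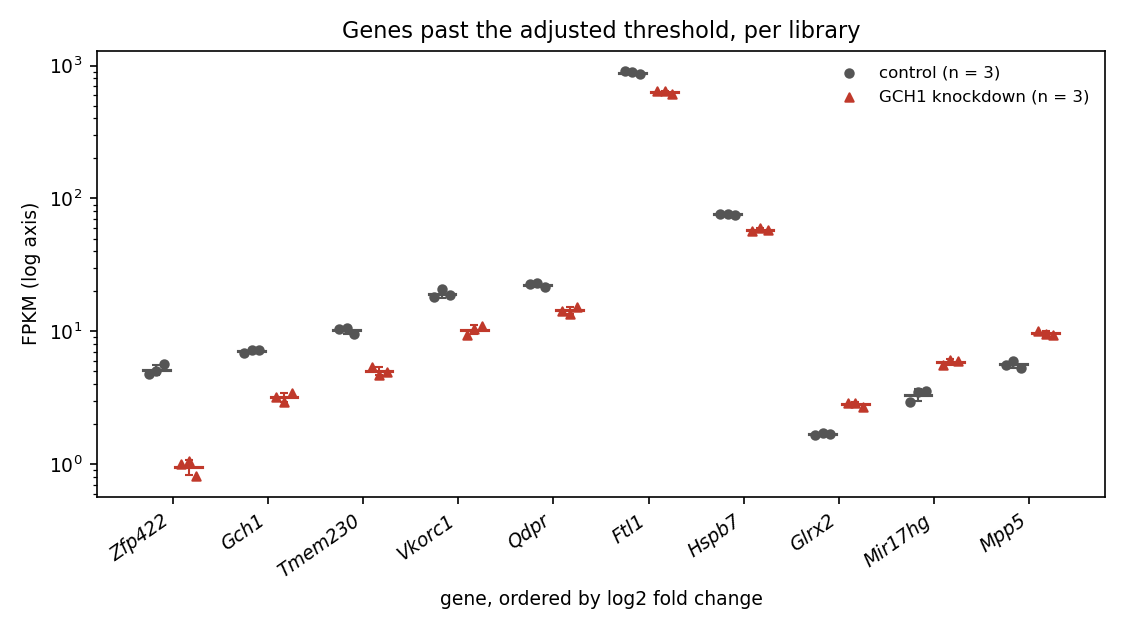
FPKM (log axis) of the 10 genes past the limma BH adjusted threshold of 0.05, ordered by log2 fold change, with control libraries as circles and knockdown libraries as triangles; horizontal lines are means and error bars SD (n = 3 each). Gch1 falls from 7.12 to 3.19 FPKM, and the groups do not overlap for any of the 10 genes.

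Within BH4 synthesis, recycling and salvage, 2 of 9 measured genes fell, Gch1 and Qdpr, and 7 did not pass; both also passed when adjusted over the list alone. Qdpr, dihydropteridine reductase, which regenerates BH4 (chromosome 5, 45434021 to 45450236, minus strand), fell from 22.4 ± 0.72 to 14.4 ± 0.88 FPKM (SD, n = 3 each), log2 -0.61 (SE 0.05, limma BH adjusted p = 0.0131). The later steps of synthesis did not pass: Pts was at a log2 fold change of 0.15 (SE 0.12) and Spr at 0.30 (SE 0.17), with limma BH adjusted p of 0.641 and 0.54. Akr1b3 was at -0.06 (SE 0.08), Cbr1 at -0.01 (SE 0.06), Pcbd2 at -0.01 (SE 0.09) and Gchfr, the feedback regulator of GCH1, at 0.00 (SE 0.16). The list as a whole had a camera BH adjusted p of 0.11. It passed lower at 0.008 with only genes of a mean of at least 5 FPKM (0.008 to 0.54 over its alternatives). That filter leaves out Spr, Pts and Gchfr. The list holds the targeted gene itself and was not tested without Gch1. Of the BH4-dependent enzymes, inducible nitric oxide synthase Nos2 was at 0.975 ± 0.129 FPKM in the controls and 1.43 ± 0.30 FPKM after knockdown (log2 0.29, limma BH adjusted p = 0.376 over all genes and 0.0467 adjusted over the list alone), and Nos1 at a log2 fold change of -0.20 (adjusted p = 0.5).

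Among the inflammatory lists, no member passed over all genes, but 13 of 16 measured pro-inflammatory cytokines and chemokines were below control, with a median log2 fold change of -0.13. Camera gave this list a BH adjusted p of 0.00012 with the preset correlation, and an adjusted p of 0.38 with an estimated correlation. The members with the smallest p were the growth factor Csf1 (log2 -0.32, SE 0.05) and the chemokines Ccl2 (-0.26, SE 0.05), Ccl4 (-0.21, SE 0.06) and Ccl7 (-0.28, SE 0.08). Csf1, Ccl2 and Ccl4 passed when adjusted over the list alone, and the limma BH adjusted p of the 4 genes over all genes was 0.156 to 0.338. In antigen presentation, 15 of 22 members were below control (median log2 fold change -0.05), led by the class I genes H2-Q4 (-0.25) and H2-K1 (-0.14), the immunoproteasome gene Psmb9 (-0.33) and the costimulatory receptor Cd40 (-0.16). Its camera BH adjusted p was 0.0046, the adjusted p with an estimated correlation was 0.38, and 1 member, H2-Q4, passed when adjusted over the list alone. Of the immediate early genes and MAPK feedback genes, 19 of 23 were below control (median log2 fold change -0.09), among them the transcription factor genes Fosl1 (-0.19) and Jund (-0.16), the RNA-destabilising factor Zfp36 (-0.18) and the MAPK inhibitor Spry4 (-0.16). That list had a camera BH adjusted p of 0.00012, an adjusted p of 0.53 with an estimated correlation and 0 members past when adjusted over the list alone. The NF-kB and Toll-like receptor list (camera BH adjusted p = 0.8; Irak4 at a log2 fold change of 0.18), interferon-stimulated genes (0.52; Oas1g at 0.26 and Oas3 at -0.17) complement (0.38; Cfp at -0.14) and alternative activation markers (0.52; Mrc1 at 0.44, the only member past when adjusted over the list alone) did not pass.

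In the growth-related lists, 38 of 41 proliferation genes were below control (median log2 fold change -0.08), with the cyclin gene Ccnd1 at -0.26 (SE 0.03, limma BH adjusted p = 0.072 over all genes, 0.038 with the GC and length trend removed in a range of 0.038 to 0.37 over its alternatives, and past when adjusted over the list alone), Cdca8 at -0.19, E2f1 at -0.14 and Mki67 at -0.18. For the proliferation list the camera BH adjusted p was 6.4e-05 and the adjusted p with an estimated correlation 0.87. Replication-dependent histones (18 of 23 below control, median log2 fold change -0.08; Hist1h1d at -0.31, Hist1h1c at -0.19) had a camera BH adjusted p of 0.025 and an adjusted p of 0.87 with an estimated correlation. Both lost the threshold without knockdown library 1. The camera BH adjusted p was then 0.06, still lower, for proliferation and 0.81, in the other direction, for histones. Proliferation passed in 5 of the 6 fits with a library left out. Histones also missed the threshold without control library 3 (0.32). Cholesterol synthesis and uptake genes (16 of 22 below control, median log2 fold change -0.05; Srebf2 at -0.14, Mvd at -0.15) had a camera BH adjusted p of 0.038 and an adjusted p of 0.53 with an estimated correlation. They did not pass without control library 2 (0.14), control library 3 (0.06), knockdown library 1 (0.062) or knockdown library 2 (0.1), with a mean of at least 5 FPKM (0.14) or without genes holding a 3′ UTR heptamer (0.059). Mitochondrially encoded genes were above control in 10 of 13 (median log2 fold change 0.09), with mt-Nd3 at 0.30 and mt-Co2 at 0.15. Their camera BH adjusted p was 0.025 and the adjusted p with an estimated correlation 0.87, and the list did not pass without control library 1 (0.29), control library 3 (0.06) or knockdown library 2 (0.44), or with quantile normalization (0.2).

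In all, 7 of the 29 lists tested passed camera with the preset correlation, 6 lower and 1 higher. With an estimated correlation 0 passed (lowest adjusted p 0.38, and 2 lists at an unadjusted p under 0.05). The estimate was 0.595 for proliferation, 0.718 for mitochondrially encoded genes and 0.89 for histones. It was 0.117 for immediate early genes, 0.05 for cytokines, 0.02 for cholesterol synthesis and 0.01 for antigen presentation. The last equals the preset, so correlation does not explain why that list was lost. With an estimated correlation camera also uses only the residual degrees of freedom, 4 here. By fry 0 passed (7 lists at an unadjusted p under 0.05), although 16 passed fry's test for change in either direction. The median, the mean and the camera direction did not all have the same sign for the NF-kB, neuropathic pain, NRF2, superoxide, ferroptosis, p53 and hypoxia lists, none of which passed camera.

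**Figure D2:**
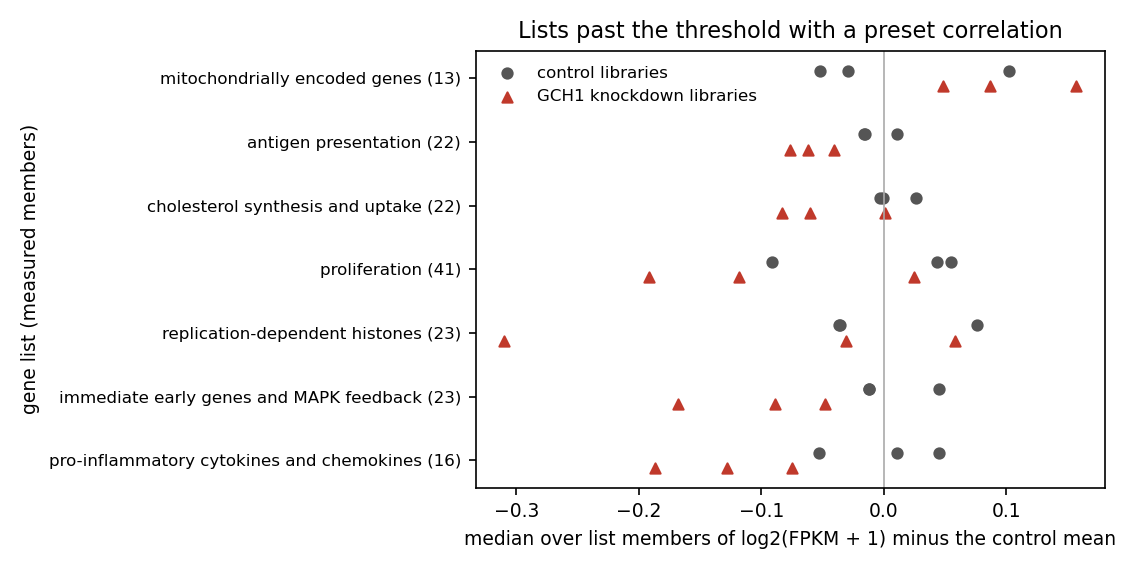
Median over the members of each list of log2(FPKM + 1) minus the control mean, for the 7 lists past a camera BH adjusted p of 0.05 with the preset correlation, with control libraries as circles and knockdown libraries as triangles. The groups do not overlap for cytokines and chemokines, immediate early genes and antigen presentation, and overlap for the other 4 lists.

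Microglial state lists did not pass as tested. Adjusted over the list alone, 0 homeostatic genes and 1 neuropathic pain gene, Ccl2, passed. Homeostatic microglial genes had a camera BH adjusted p of 0.8 (Aif1 at a log2 fold change of 0.24, Csf1r at 0.07), disease-associated microglial genes 0.11 (Spp1 at -0.25 and Ctsd at -0.22, with Csf1 among the 2 members that passed when adjusted over the list alone; the list passed without control library 2, at 0.044, and without genes holding a 3′ UTR heptamer, at 0.034, in a range up to 0.87) and microglial genes of neuropathic pain 0.49 (Tnf at -0.24 and Mapk14 at -0.65, SE 0.18, which passed only without control library 3, at a limma BH adjusted p of 0.025, in a range of 0.025 to 0.53 over its alternatives). Lists of other cell types had 0 to 2 measured members, too few to test: Aldoc for astrocytes, Cnp for oligodendrocytes, Acta2 for fibroblasts and mural cells, Vwf and Flt1 for endothelial cells, Lck for lymphocytes and none for neurons. Their log2 fold changes ranged from -0.18 for Lck to 0.13 for Vwf, and none passed.

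Of 1514 noncoding and predicted genes tested, 1 passed, Mir17hg (ENSMUSG00000089726.2; chromosome 14, 115042879 to 115046727, plus strand), which rose from 3.33 ± 0.34 to 5.88 ± 0.29 FPKM (SD, n = 3 each), log2 0.67 (SE 0.07, limma BH adjusted p = 0.0403). At an unadjusted p under 0.05, 219 noncoding genes were higher and 38 lower, and the median log2 fold change of the class was 0.06, against 0.00 for protein-coding genes. Among well-known long noncoding RNAs (camera BH adjusted p = 0.39), Snhg3 was at a log2 fold change of 0.39, Snhg17 at 0.22 and Neat1 at -0.26, and 4 of 25 passed when adjusted over the list alone.

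The libraries also differed along the GC content of transcripts, partly with the groups. Protein-coding genes were divided into 5 groups of like size by GC content. The median log2 fold change was 0.05 in the lowest group (median GC 41.7%) and -0.04 in the highest (58.1%). Spearman's rho between fold change and GC content was -0.30 across 10684 genes, which are not independent replicates. Control 2 tilted the same way as knockdown 1 and knockdown 2, and controls 1 and 3 the other way. With this trend and that of length removed, the noncoding median was 0.00 and Mir17hg, Glrx2 and Ftl1 no longer passed (limma BH adjusted p = 0.11, 0.056 and 0.056). The larger noncoding classes differed. The median stayed positive for lincRNA (0.08 before, 0.035 after) and processed transcripts (0.07 and 0.039). It turned negative for the TEC biotype (0.054 and -0.006) and sense intronic transcripts (0.021 and -0.036). The mitochondrial list turned to the other direction (camera BH adjusted p = 0.62), and cholesterol synthesis missed the threshold (0.055). The other 5 lists passed, cytokines at 6.6e-06, proliferation at 4e-05, immediate early genes at 0.0015, and antigen presentation and histones at 0.0068 each. With an estimated correlation none of these 5 passed after the removal, at an adjusted p of 0.23, 0.84, 0.51, 0.34 and 0.88 in that order.

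**Figure D3:**
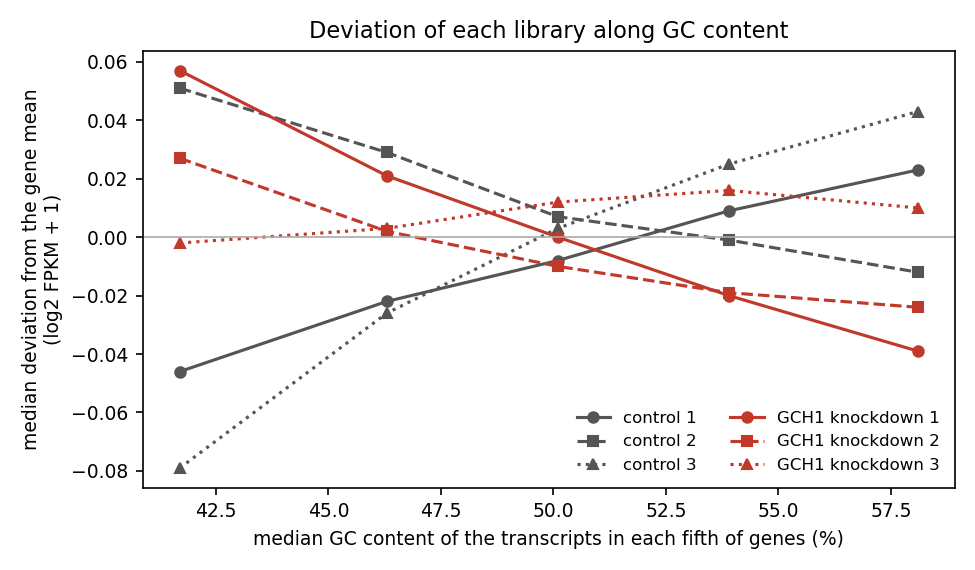
Median deviation from the mean of the 6 libraries, in log2(FPKM + 1), of protein-coding genes in 5 groups by transcript GC content, against the median GC content of each group in percent, with 1 line per library. Control 1 and control 3 rise with GC content, control 2, knockdown 1 and knockdown 2 fall, and knockdown 3 stays between -0.002 and 0.016.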

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

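The GC and length correction and the test without heptamer genes were chosen after the data were seen. With each library left out in turn, 6 to 18 genes passed the limma threshold (18 without control library 2, and 6 without knockdown library 2 or 3), 6 to 16 with at least 1.5-fold change (16 without control library 2, 12 without control library 3), 4 to 7 lists (4 without control library 3) and 0 to 1 noncoding genes. The log2 fold change of Gch1 then stayed between -0.999 and -0.911. The histone list ranged from a camera BH adjusted p of 2.8e-06 to 0.81, where it turned higher without knockdown library 1. Genes shared with the 10 reported numbered 3 to 7 in these fits, which had fewer libraries. No noncoding gene passed, a count of 0, with a mean of at least 5 FPKM, which removes Mir17hg, Glrx2 and Zfp422 before the test (791 genes of any class at an unadjusted p under 0.05), or with the GC and length trend removed (1508 genes). In the latter, 8 genes passed, 7 of them among the 10, and the mitochondrial list turned lower (camera BH adjusted p = 0.62, range 0.0024 to 0.87 over its alternatives). No list passed, again 0, with camera's estimated correlation or with fry, against 7 as reported. Between 7 and 11 genes passed in the other fits without a block, and with a pseudocount of 0.1 or 0.5 the genes of 1.5-fold numbered 8. Of 2019 comparisons of named genes with their reported values, 42 lost the threshold, 3 gained it and 0 called genes changed sign, while 25 uncalled ones did. Of the list tests, 28 lost the threshold in the same direction, the 2 that turned direction lost it too, and 5 gained it. Values near the lower limit of 0.5 FPKM rest on few reads, and their number is unknown.

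The replicate numbers of the titles were tried as a block. Deviations from the group means correlated at 0.09, 0.06 and 0.09 across genes between libraries with the same number, each library correlating best with its own number, a hint from the data and not from the design. Pairs with different numbers correlated at -0.1 to 0.01. No label gives the numbers a meaning, so whether libraries with the same number share more than that is unsettled. With the block, 0 genes passed limma's adjusted threshold (0 with 1.5-fold change and 0 noncoding), 1330 genes had an unadjusted p under 0.05 and 6 lists passed, without cholesterol synthesis (camera BH adjusted p = 0.056, 0.014 to 0.53 over its alternatives). Gch1 was at -0.956 with a limma BH adjusted p of 0.06 (0.0022 to 0.06 over its alternatives), in a fit with fewer residual degrees of freedom.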

Other observations

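The tests of the GC correction, of the splits for the count of genes past the threshold and for the heptamer, and the search for heptamers itself were chosen after their results, or the values behind them, had been seen. Lists of energy, redox and stress genes other than the mitochondrially encoded genes described above did not pass camera over the 29 lists as tested. The list of nuclear-encoded oxidative phosphorylation genes had a camera BH adjusted p of 0.38, with the complex III gene Uqcrh (log2 fold change 0.32, SE 0.04) and the complex IV gene Cox7a2 (0.22) past when adjusted over the list alone. Without knockdown library 1 this list passed higher at 0.0091 (up to 0.93 over its alternatives), and cytosolic ribosomal proteins at 0.047 (up to 0.99). Glycolysis (0.39) was led by Hk3 at -0.16 and Pfkfb3 at -0.46, hypoxia (0.88) by Pdk1 at 0.14, and cytosolic ribosomal proteins (0.62) by Rps25 at 0.15. The NRF2 list (0.52) held Ftl1, which fell, and the haem oxygenase Hmox1 at -0.16, and both passed when adjusted over the list alone. In ferroptosis (0.88) the transferrin receptor Tfrc was at 0.27 and the ferritin receptor Ncoa4 at -0.69 (SE 0.24), which passed without knockdown library 2 (log2 -1.01, limma BH adjusted p = 0.0068, 0.0068 to 0.64 over its alternatives). Superoxide and nitric oxide handling (0.8) was led by Ddah1 at -0.15, phagocytosis and lysosome (0.36) by Ctsd at -0.22, and purine synthesis (0.52) by Pfas at -0.14. Targets of p53 (0.8; Plk2 at -0.20), the unfolded protein and integrated stress response (0.41; Dnajb9 at 0.22), heat shock (0.88; Hspa8 at -0.14) and LXR targets and fatty acid synthesis (0.47; Srebf1 at -0.10) did not pass either. Beyond the members named as passing, Hmox1 in the ferroptosis list was the only member of these lists past when adjusted over its list alone.

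The mitochondrial gene mt-Atp6 split the libraries without regard to group. It was at 368, 370 and 363 FPKM in control 1, knockdown 1 and knockdown 3, and at 1381, 1220 and 1431 FPKM in control 2, control 3 and knockdown 2. The gene mt-Atp8, which overlaps it on the same strand (GRCm38 mitochondrial genome, 7766 to 7969, against 7927 to 8607 for mt-Atp6), did not split in this way, at 910 to 1047 FPKM in the controls and 1096 to 1323 FPKM after knockdown. The mt-Atp8 change (log2 0.37) passed when adjusted over the mitochondrial list alone, but its limma BH adjusted p over all genes was 0.287, and that of mt-Atp6 was 0.775.

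The first pattern weighed was the set of 10 genes past the threshold. With the GC and length trend removed, 91.9% of their median absolute log2 fold change was left, which argues against that trend as the whole cause, although 3 calls ended: Ftl1 (-0.49, SE 0.04 before and 0.05 after), Glrx2 (0.51 to 0.47, SE 0.05 both times) and Mir17hg (0.67 to 0.61, SE 0.07 to 0.09). Their limma statistics went from -12.1 to -9.25, 9.51 to 9.19 and 9.21 to 7.17, and the prior degrees of freedom from 3.12 to 2.66, which raises p at a given statistic; how much each contributed was not separated. Reads shared with a measured overlapping gene are argued against: 0 of the 10 genes overlap a measured gene on the same strand, whichever way it moved. On the opposite strand only Ftl1 overlaps one, Gm10252 (2.39 FPKM in the controls and 2.46 FPKM after knockdown). That is too weak for the fall of Ftl1 from 887 to 630 FPKM. Overlap with genes that were not tested was not searched and stays open. Pairing of the heptamer described below with 3′ UTRs does not account for all 6 genes that fell beside Gch1. Only 1 of them (16.7%, upper 95% limit 64.1%), Zfp422, holds it, against 16.9% of searched genes (exact hypergeometric p = 0.67). For Zfp422 alone that pairing stays open. The heptamer was found in these data, and the hairpin sequence was not used. Pairing of the hairpin with these genes through another sequence therefore stays open. An effect of the knockdown, of adenoviral infection if the control cells had none, and of chance in the count stay open: 2 of the 10 splits of the 6 libraries gave at least 10 genes, the highest other 12, and 2 gave at least 7 genes of 1.5-fold, the highest other 10, while the 1 noncoding call stands against 0 in every other split, and 10 splits are too few for a share under 0.05.

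The next pattern was the lower level of cytokines and chemokines, immediate early genes and antigen presentation genes, the lists that passed with every single library left out. The GC and length trend is argued against as the whole cause, since 3 of the 3 lists still passed camera at the preset correlation after its removal, as before it; with an estimated correlation none passed before (adjusted p 0.38, 0.53 and 0.38) or after (0.23, 0.51 and 0.34). Pairing of the heptamer with the 3′ UTRs of the lists' own members is argued against as the whole cause too. Without the members that hold it, 3 of the 3 passed at the preset correlation, with camera BH adjusted p of 0.0011, 0.00076 and 0.0016. Over all alternatives the range was 6.6e-06 to 0.38 for cytokines, 4.3e-05 to 0.53 for immediate early genes and 0.0016 to 0.38 for antigen presentation. An effect through other genes that hold the heptamer was not tested. Whether any list stands apart at all stays open, because 7 lists passed in the real split and 9 in the split of control 1, control 3 and knockdown 3 from the rest, 2 of the 10 splits gave at least 7, and 10 splits are too few for a share under 0.05. Effects of the knockdown and of the infection stay open too and were not tested apart, and the NF-kB and Toll-like receptor (camera BH adjusted p = 0.8), interferon (0.52) and complement (0.38) lists did not pass.

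The last pattern was a small shift in genes by 3′ UTR sequence. Of 16046 heptamers, TCCATTT had the lowest z on GC- and length-corrected values (-7.43), but not without that correction, where it was at -6.56, CTCTCCC at -6.92 and CCCACCC at -6.89. The 1776 of 10496 searched genes that hold TCCATTT had, on corrected values, a median log2 fold change of -0.01, and 55.9% of them were lower, against 50% of the others. Base composition is argued against, since z was -7.21 with dinucleotide frequencies and length as terms, and so is a trend on either strand, since the reverse complement AAATGGA had a z of 0.30. TCCATTT occurs 1 time in the Gch1 mRNA, starting at base 557 of 2775, as 15.2% of all heptamers do at least that often. Pairing of the hairpin's seed with unintended 3′ UTRs may be a candidate explanation. Genes with at least 2 copies lay lower than genes with 1 copy (one-sided permutation p = 0.032). Their median log2 fold changes on corrected values were -0.016 and -0.01. The permutation shuffled genes, which are not independent replicates, and the heptamer was picked from the same values. Copies in coding sequence showed no such shift (z = 0.59). The outcome set before that test as going against pairing in coding sequence was met. A z this small cannot tell an absent effect from a small one, so such pairing stays open. The hairpin sequence was not used here, z ranged from -7.45 to -5.71 with single libraries left out, and of the 10 splits only the real one, 1 in all, gave an absolute z as high as 7.43 (highest other 5.72), too few splits for a share under 0.05, while TCCATTT was also farthest from 0 (z = -5.14) in the mixed split of control 1, control 2 and knockdown 2 from the rest.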
